A study of Ctenopharyngodon idella and Danio rerio with 13 samples.

How the data were processed

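RNA of 13 sperm libraries was sequenced, each made from the sperm of 1 fish: 3 zebrafish that carried transplanted grass carp germline stem cells (GSCT, germline stem cell transplantation), 5 grass carp and 5 zebrafish. Per the labels' protocols, a small volume of diluted sperm went directly into a full-length mRNA amplification kit designed for single cells, and the cDNA was made into an Illumina library. The labels' protocols count as many fish of each kind as there are libraries, so the replicates are different fish. The deposited files hold raw read counts per gene, 1 file per library, over the same 31338 entries in the same order. The submitters' processing notes name CASAVA, FastQC, fastp, HISAT2, SAMtools, featureCounts and Subread, without versions or roles. The genome build, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so no coordinates are reported, and genes with near-identical copies, overlapping genes and antisense pairs are uncertain.

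The gene symbols of the files were compared with a grass carp RefSeq gene table (assembly HZGC01). All 29689 named entries other than tRNA genes matched a symbol in it, the 1625 tRNA entries matched in number per symbol, and the order was the same. The zebrafish libraries were therefore counted on grass carp genes too, and their counts depend on which zebrafish reads align to another species' genes. That table was used only for gene type, gene span and which genes are neighbours. A further 24 entries carry no gene name and were left out of library sizes and tests. Which genes they stand for is not known here, and shares of counts on mitochondrial and rRNA genes cover named entries only. The unnamed entries held a mean of 57.7% ± 25.2 (SD, n = 5) of the counts in zebrafish libraries. In GSCT libraries they held 0.404% ± 0.256 (SD, n = 3; 0.266 without replicate 1) and in grass carp libraries 0.0424% ± 0.0562 (SD, n = 5; 0.0184 without replicate 1).

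Total counts on named genes ranged from 376926 to 2602370 in GSCT, from 1335167 to 5471312 in grass carp and from 487 to 248321 in zebrafish libraries. With a floor of 3 counts, a gene at 0 was below 1.15 to 7.96 CPM (counts scaled to library size) in a GSCT library, below 0.548 to 2.25 in a grass carp library and below 12.1 to 6160 in a zebrafish library. Shares of counts in single libraries carry Wilson intervals at the 95% level. Amplified reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. No 2 libraries held identical counts.

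Each pair of groups was compared with edgeR 4.0.16 (R 4.3.3): only the libraries of those groups, TMM factors, the default filter by group (minimum count 10, minimum total count 15), the quasi-likelihood F test (glmQLFit and glmQLFTest), and Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2, first group minus second. CPM values in the text are scaled to the total of named counts. Where a group had no counts on a gene, the fold is given as a lower bound against 3 counts over the whole group. Similarity was the Pearson correlation across genes of log2(CPM + 1), and the difference of means was tested by an exact two-sided permutation of the grass carp and zebrafish labels. Totals and detected genes were compared by exact two-sided permutation tests, adjusted over 9 tests. The same tests of the shares of counts on mitochondrial and rRNA genes, adjusted over 6, were added after the data were examined.

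Gene lists fixed before the data were examined were tested with camera (preset correlation 0.01) in limma 3.58.1, adjusted over the lists within a comparison, with camera at an estimated correlation and fry beside it. A list with fewer than 3 tested members was counted but not tested. The lists, 17 in number, are sperm axoneme and flagellum, sperm head (with fertilization and spermatid genes), germ cells and meiosis, oocyte and egg, testis somatic cells, and blood cells. Others are leukocytes, epithelium (with muscle and kidney), mitochondrial genome, nuclear oxidative phosphorylation, cytosolic ribosomal proteins and proteasome. The rest are glycolysis and creatine kinase, heat shock and immediate early stress, histones and chromatin, RNA binding and translation factors, and sex determination pathway. Genes were eligible for naming by a rule set before the data were examined. It took the 6 largest rises and 6 largest falls among genes past the threshold with a symbol, a mean CPM of 20 or more in the higher group and no overlap between the groups' libraries. It also took up to 4 members of each list with the lowest p and the 10 most abundant genes of each group. Which of these genes the text names was chosen after their values were seen. Of the eligible genes 1 is not reported here, though totals over all genes or over a list still count it.

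The comparison was tested on simulated counts with known changes of 100 genes at each of 2 sizes. Both groups of a comparison had the proportions of its first group and 1 spread for all genes. Simulated zebrafish libraries thus had GSCT or grass carp proportions, and recovery in the real libraries may differ. For GSCT against grass carp (28029 genes tested), 58 of 100 genes changed by 1 log2 unit and 96 of the 97 tested genes changed by 2 log2 units were recovered. For GSCT against zebrafish (8300 genes) 0 of 90 and 2 of 84 tested genes were recovered, and for grass carp against zebrafish (21691 genes) 3 of 84 and 60 of 68. Alternatives were DESeq2 1.42.0, RLE factors, library size alone, no filter, a stricter filter (CPM of 5 in 3 libraries), all 3 groups in 1 fit, a test against a log2 change of 1, thinning, a replicate block, and leaving out each library. Those added after the data were examined were keeping the unnamed entries, thinning without the shallowest libraries, and leaving out mitochondrial and rRNA genes.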

Results

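Read counts per gene were compared in sperm from zebrafish that had received grass carp germline stem cells, from grass carp and from zebrafish. The study set out to examine how alike the 3 kinds of sperm are. There were 3 GSCT, 5 grass carp and 5 zebrafish libraries. Mean total counts were 1705806 ± 1174020 (SD, n = 3) in GSCT and 4209677 ± 1732922 (SD, n = 5) in grass carp libraries. Zebrafish libraries held 119371 ± 98302 (SD, n = 5), and zebrafish replicate 3 held only 487 counts.

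At least 1 count was found on 29373 ± 1040 genes in GSCT libraries (SD, n = 3), on 29968 ± 223 in grass carp libraries (SD, n = 5) and on 3779 ± 2255 in zebrafish libraries (SD, n = 5). Lists that mark unlike cell types were all covered in GSCT and grass carp libraries. The median of sperm axoneme and flagellum genes was 29.8 ± 2.59 CPM in GSCT (SD, n = 3) and 30.6 ± 1.83 CPM in grass carp (SD, n = 5). That of leukocyte genes was 20.3 ± 1.87 and 23.4 ± 0.819 CPM, and that of oocyte and egg genes 14.9 ± 1.16 and 15.7 ± 1.23 CPM. All protein-coding genes had medians of 26.7 ± 0.559 and 28.3 ± 0.626 CPM, lower in every GSCT library. So were the medians of 6 of the 17 lists: germ cells (28.4 ± 3.06 and 36.3 ± 1.599 CPM), leukocytes, nuclear oxidative phosphorylation, proteasome, histones, and RNA binding factors. In 2 lists, the mitochondrial genome and sex determination, every GSCT library was higher, and chance gives such a separation in 3.57% of cases. For sex determination the groups nearly touched, with the lowest GSCT median at 22.55 CPM and the highest grass carp median at 22.46 CPM. Cytosolic ribosomal protein genes, highly transcribed in many cells, had medians of 9.54 ± 1.37 CPM in GSCT and 10.8 ± 0.652 CPM in grass carp, against 94.4 ± 123 CPM in zebrafish libraries (SD, n = 5; 46.2 without replicate 2). Zebrafish replicates 3 (0 CPM) and 4 (9.475 CPM) lay below every grass carp library.

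Counts rose with gene span across genes, which are not independent replicates. The mean Spearman rho was 0.631 ± 0.0240 in GSCT (SD, n = 3), 0.657 ± 0.0175 in grass carp (SD, n = 5) and 0.193 ± 0.104 in zebrafish libraries (SD, n = 5). Reads from genomic DNA, taken up below, are a candidate source of the counts in GSCT and grass carp libraries. Rises and falls given here are therefore changes of counts, whatever their source. A difference between GSCT and grass carp libraries in total counts did not pass (exact permutation p = 0.0893, adjusted p = 0.115), nor did one in detected genes (exact p = 0.179, adjusted p = 0.201). The smallest p these splits allow was 0.0179. Without grass carp replicate 4 the difference in totals was -3222499 counts (exact permutation p = 0.0286). GSCT exceeded zebrafish libraries in totals and detected genes at the smallest p possible (exact p = 0.0179, adjusted p = 0.0268). Grass carp exceeded zebrafish libraries in both as well (exact p = 0.00794, the smallest possible, adjusted p = 0.0238).

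**Figure D1:**
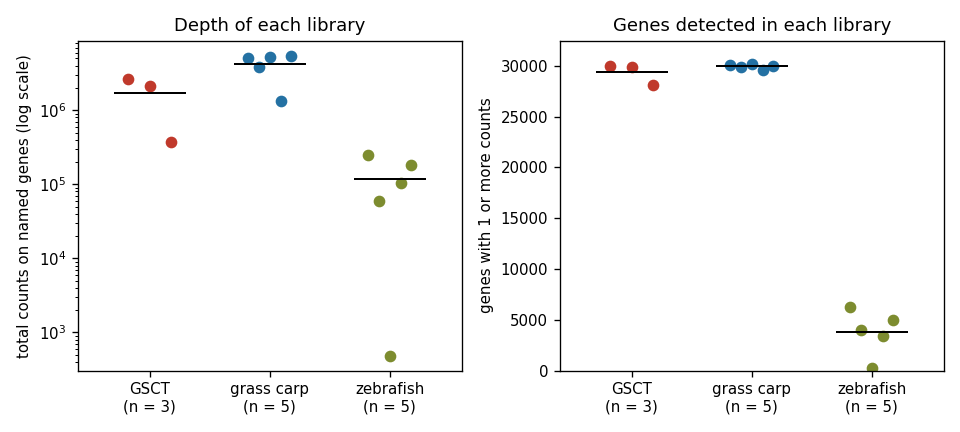
Total counts on named genes (left, log axis) and number of genes with at least 1 count (right) in each library of the 3 groups, with points for libraries and lines for group means. Zebrafish libraries lie below all others in both panels.

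**Figure D2:**
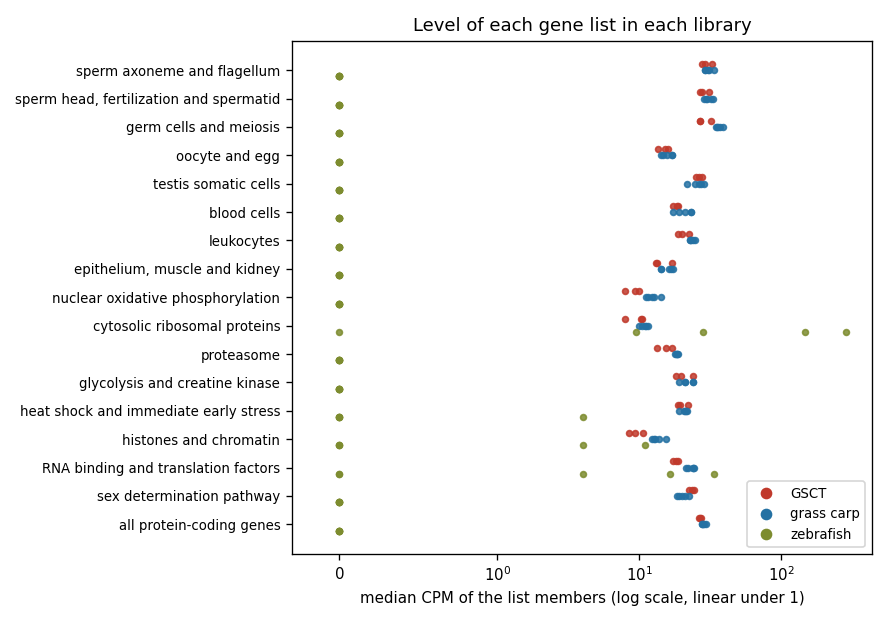
Median CPM of the members of each gene list in each library (horizontal axis, logarithmic above 1), with 1 point per library and the mitochondrial genome list left out. GSCT and grass carp libraries lie close together for several lists of unlike cell types, while most zebrafish medians are at 0.

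GSCT libraries were closer to grass carp than to zebrafish libraries. Across 26159 genes, the mean correlation of GSCT with grass carp libraries was 0.851 ± 0.0498 (SD over 15 pairs) and with zebrafish libraries 0.121 ± 0.0718 (SD over 15 pairs). The difference of 0.730 was at the smallest p that permutation can give (exact p = 0.00794), and it pointed the same way in each of the 3 GSCT libraries. Grass carp libraries correlated with each other at 0.933 ± 0.0139 (SD over 10 pairs), GSCT libraries at 0.875 ± 0.0580 (SD over 3 pairs) and zebrafish libraries at 0.442 ± 0.198 (SD over 10 pairs). The first principal component held 85.9% of the variance. Grass carp libraries correlated with zebrafish libraries at 0.131 ± 0.0792 (SD over 25 pairs), close to the value of GSCT libraries. The zebrafish correlations rest on counts of zebrafish reads on grass carp genes and on their low depth. The permutation test therefore cannot tell alike expression from alike alignment.

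**Figure D3:**
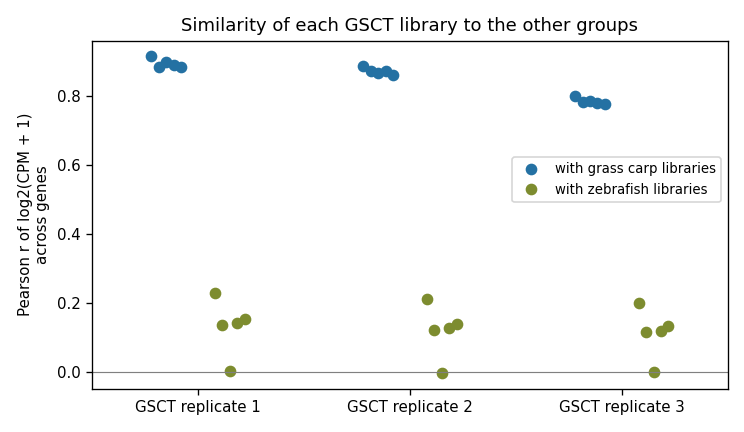
Pearson correlation across genes of log2(CPM + 1) between each GSCT library (horizontal axis) and each grass carp or zebrafish library, with 1 point per pair. Every correlation with a grass carp library (lowest 0.776) is above every correlation with a zebrafish library (highest 0.227).

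The comparison of GSCT with grass carp sperm asked how sperm made in a surrogate host differ from those of the donor species. Among genes with a symbol, mitochondrial genes stood furthest apart. All 13 protein-coding genes of the mitochondrial genome, which encode subunits of the respiratory chain and ATP synthase, were higher in GSCT (13 of 13 adjusted over the list alone). They made up 1.21% ± 0.587 of counts in GSCT (SD, n = 3) and 0.0195% ± 0.00766 in grass carp (SD, n = 5), a difference at the smallest p possible (exact permutation p = 0.0179, adjusted p = 0.0268). In zebrafish libraries they made up 0.0109% ± 0.0141 (SD, n = 5; 0.00688 without replicate 2 and 0.00723 without replicate 5). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, ND6 rose by 6.49 ± 0.30 (log2, SE; adjusted p = 1.51e-11), ND5 by 6.34 ± 0.35 (adjusted p = 1.11e-10) and CYTB by 6.28 ± 0.31 (adjusted p = 2.99e-11). Genes for ribosomal RNA rose too, 44 of 51 tested. They took 1.501% ± 0.441 of counts in GSCT (SD, n = 3) and 0.0769% ± 0.0258 in grass carp (SD, n = 5; exact permutation p = 0.0179, adjusted p = 0.0268). In zebrafish libraries rRNA took 42.7% ± 30.9 (SD, n = 5).

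Of 28165 genes tested, 1223 passed adjusted p under 0.05, 984 higher and 239 lower in GSCT, and 5629 had an unadjusted p under 0.05. Scaling by library size alone gave 718 higher and 422 lower. The count fell to 285 without GSCT replicate 2, 679 without GSCT replicate 1, 812 without GSCT replicate 3 and 802 without grass carp replicate 5.

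**Figure D4:**
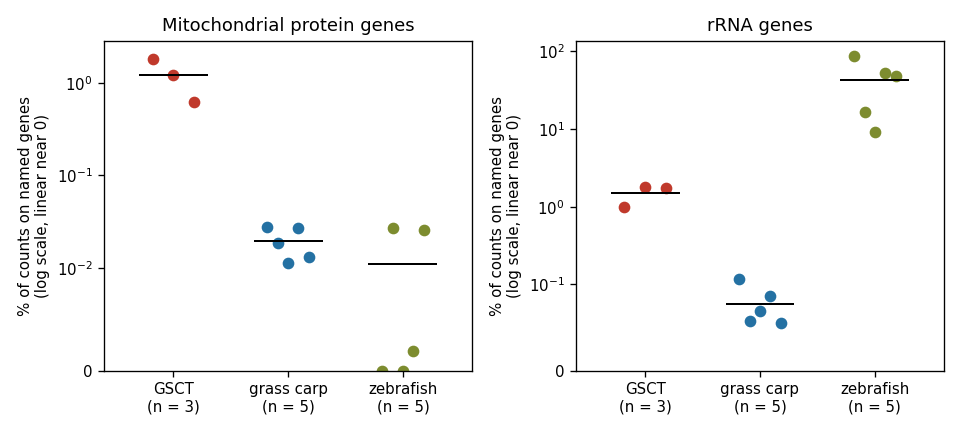
Share of counts on the 13 mitochondrial protein genes (left) and on rRNA genes (right) in each library, in percent on axes that are logarithmic above a small linear part, with lines for group means. All 3 GSCT libraries lie above all 5 grass carp libraries in both panels.

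Outside the mitochondrial genome, the largest falls in GSCT among genes with a symbol, under the rule for naming, were as follows, all log2 with SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The first was gbf1, an activator of ARF proteins in Golgi transport (-3.45 ± 0.47, adjusted p = 1.24e-04) and the next plxnb1a, a semaphorin receptor (-3.40 ± 0.87, adjusted p = 0.0286). Others were pla2g7, a phospholipase (-2.51 ± 0.46, adjusted p = 0.00238), ptpn1, a tyrosine phosphatase (-2.51 ± 0.35, adjusted p = 1.38e-04), caprin2, an RNA-binding protein (-2.33 ± 0.39, adjusted p = 0.00119), and ier3, an immediate early gene (-2.31 ± 0.52, adjusted p = 0.0138). Levels of plxnb1a varied widely, at 6732 ± 8144 CPM in grass carp (SD, n = 5; 3128.5 without replicate 1) and 607.0 ± 840.0 CPM in GSCT (SD, n = 3; 122.1 without replicate 1). The fall of plxnb1a did not pass without GSCT replicate 2 (-2.93, edgeR adjusted p = 0.186) or replicate 3 (-2.93, adjusted p = 0.127). That of pla2g7 did not pass without GSCT replicate 2 (-2.47, edgeR adjusted p = 0.0512), nor that of ier3 without GSCT replicate 1, 2 or 3 (-2.58, -2.14 and -2.29, adjusted p = 0.0818, 0.169 and 0.05004).

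Among sperm and germ cell genes few passed, which does not show alike transcript levels where counts may come from genomic DNA. In the axoneme list 1 of 49 tested members rose (1 adjusted over the list alone). It was dnaaf1, needed for assembly of dynein arms, at 0.90 ± 0.19 (edgeR, adjusted p = 0.00728). Of 27 sperm head and spermatid genes 0 passed (0 adjusted over the list alone), with spata7 at -0.75 ± 0.23 (edgeR, adjusted p = 0.0657). Of 33 germ cell and meiosis genes 2 fell (3 adjusted over the list alone). They were tdrd6, a tudor protein of germ granules (-1.47 ± 0.33, edgeR adjusted p = 0.0138), and sycp1, of the synaptonemal complex (-0.64 ± 0.18, adjusted p = 0.0447). That list missed the threshold by camera (adjusted p = 0.0512, and adjusted p = 0.167 with an estimated correlation). It fell by fry, which does not compare it with other genes (adjusted p = 0.0257). Both genes lost the call when any 1 GSCT library was left out, at most with edgeR adjusted p = 0.101 for tdrd6 and 0.2996 for sycp1 without GSCT replicate 2. The log2 changes then ran from -1.569 to -1.431 for tdrd6 and from -0.84 to -0.54 for sycp1. The call of sycp1 was also lost without grass carp replicate 1 (adjusted p = 0.0794) or 3 (adjusted p = 0.0823).

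Of 29 heat shock and immediate early genes 2 rose (2 adjusted over the list alone). They were hsp70.3, a chaperone (1.09 ± 0.20, edgeR adjusted p = 0.00291), and fosaa, a transcription factor subunit (0.70 ± 0.14, adjusted p = 0.00576). The list had camera adjusted p = 0.183 and fry adjusted p = 0.0257. Among RNA binding and translation factors 1 of 37 fell (2 adjusted over the list alone; camera adjusted p = 0.0964). It was eif4ebp3l, a repressor of cap-dependent translation (-1.14 ± 0.18, edgeR adjusted p = 5.79e-04). In glycolysis and creatine kinase 1 of 39 fell (1 adjusted over the list alone; camera adjusted p = 0.151), ckba (-2.16 ± 0.41, edgeR adjusted p = 0.00379). In nuclear oxidative phosphorylation 1 of 54 fell (0 adjusted over the list alone; camera adjusted p = 0.151), ndufs4 (-1.27 ± 0.34, edgeR adjusted p = 0.0350). Of 17 blood genes 1 fell (1 adjusted over the list alone; camera adjusted p = 0.438), alas2, which starts heme synthesis (-1.22 ± 0.31, edgeR adjusted p = 0.0288). Without GSCT replicate 2 edgeR lost fosaa (adjusted p = 0.0565), ckba (adjusted p = 0.0939), ndufs4 (adjusted p = 0.169) and alas2 (adjusted p = 0.146). It also lost ndufs4 without GSCT replicate 1 (adjusted p = 0.118), GSCT replicate 3 (adjusted p = 0.0596) or grass carp replicate 5 (adjusted p = 0.0610). It lost alas2 without GSCT replicate 1 as well (adjusted p = 0.194).

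In 9 lists 0 members passed by edgeR's quasi-likelihood test, over all genes or adjusted over the list alone, and 0 by DESeq2. At an unadjusted p under 0.05 there were 2 of 27 sperm head genes (camera adjusted p = 0.741), 3 of 22 oocyte and egg genes (adjusted p = 0.912) and 3 of 24 testis somatic genes (adjusted p = 0.741). There were 7 of 31 leukocyte genes (camera adjusted p = 0.102), 6 of 27 epithelium, muscle and kidney genes (adjusted p = 0.309) and 4 of 83 ribosomal protein genes (adjusted p = 0.523). There were 6 of 50 proteasome genes (camera adjusted p = 0.412), 1 of 13 histone and chromatin genes (adjusted p = 0.183) and 2 of 19 genes of sex determination (adjusted p = 0.438). The axoneme list had camera adjusted p = 0.912. Of the 17 lists 1 passed, the mitochondrial genome (camera adjusted p = 5.28e-53, and adjusted p = 0.0499 with an estimated correlation).

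**Figure D5:**
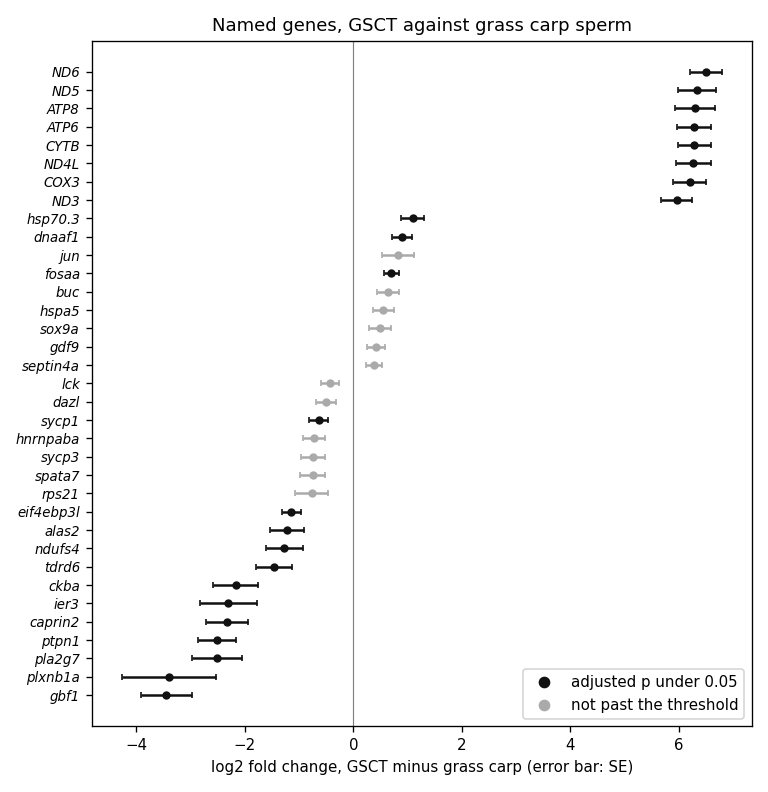
Log2 fold change of named genes in GSCT against grass carp sperm (horizontal axis), with SE as error bars, black for adjusted p under 0.05 by edgeR's quasi-likelihood test and grey otherwise. Mitochondrial genes lie near 6, and all other genes shown lie between -3.45 and 1.09.

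The comparison of GSCT with zebrafish sperm asked how far the surrogate's sperm differ from those of its own species. The mitochondrial genes ND5, CYTB and COX3 were at 0 in zebrafish libraries. GSCT exceeded 3 counts over the zebrafish group by at least 408-fold for ND5, 248-fold for CYTB and 162-fold for COX3. Because zebrafish reads were counted on grass carp genes, a 0 in zebrafish libraries may reflect reads that did not align, not an absent transcript. Such folds bound the counts and not the expression. Of the mitochondrial genes 12 of 12 tested were higher in GSCT (12 adjusted over the list alone; camera adjusted p = 1.69e-10, and adjusted p = 0.164 with an estimated correlation). The germ cell genes ddx4 (vasa) and msh5, of meiotic recombination, were also at 0 there, and at least 13.1-fold and 19.4-fold higher in GSCT. Another germ cell gene, sycp1, was at 26.5 ± 4.64 CPM in GSCT (SD, n = 3) and at 0 to 2293.1 CPM in zebrafish libraries. Ribosomal protein genes went the other way: without a filter 64 of all 83 were lower in GSCT and 4 higher (edgeR; camera adjusted p = 1.92e-17). Their zebrafish median was not above the GSCT mean of 9.54 CPM in replicates 3 (0 CPM) and 4 (9.475 CPM), though replicate 4 was above GSCT replicate 3 (7.959 CPM). Cytoplasmic actin, actb2, was at 9.88 ± 1.87 CPM in GSCT (SD, n = 3) and 26959 ± 29572 CPM in zebrafish libraries (SD, n = 5; 15218.3 without replicate 3), with edgeR adjusted p = 0.00113.

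Of 5622 genes tested by edgeR's quasi-likelihood test, 4906 passed the adjusted threshold, 4347 higher and 559 lower in GSCT. Other scalings gave fewer lower: 5102 higher and 151 lower by DESeq2, 5136 and 162 by RLE factors, and 5050 and 212 by library size alone. No zebrafish library had a count on 2467 of the tested genes. The filter asks for about 46.3 CPM in 3 libraries, so a gene low in GSCT is tested only if it is high in zebrafish libraries, and the directions of such lists follow in part from the filter. With it 41 of 41 ribosomal protein genes were lower (41 adjusted over the list alone; camera adjusted p = 1.25e-118, and adjusted p = 0.00835 with an estimated correlation). Of RNA binding and translation factors 8 of 10 were lower and 1 higher (the same adjusted over the list alone; camera adjusted p = 2.51e-17, and adjusted p = 0.0175 with an estimated correlation), but without a filter 16 of 37 were lower and 9 higher (adjusted p = 0.02905). Of these rack1, a ribosomal scaffold, was at 10.5 ± 3.41 CPM in GSCT (SD, n = 3) and 2040 ± 1628 CPM in zebrafish (SD, n = 5; edgeR adjusted p = 0.00107). Of 5 heat shock and immediate early genes 3 were lower and 1 higher (3 and 1 adjusted over the list alone; camera adjusted p = 5.33e-05, and adjusted p = 0.0175 with an estimated correlation), but without a filter 7 of 29 were lower and 15 higher (adjusted p = 0.5396). In the axoneme list 11 of 19 were higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.788). Its hydin, of the ciliary central pair, was at 206 ± 9.93 CPM in GSCT (SD, n = 3) and 0.805 ± 1.80 CPM in zebrafish (SD, n = 5), where its only count was 1 in replicate 1. Camera gave adjusted p = 0.7002 for germ cell, 0.596 for testis somatic, 0.596 for leukocyte and 0.591 for glycolysis genes. It gave adjusted p = 0.572 for sex determination and 0.778 for sperm head genes. Fewer than 3 members were tested in the oocyte, blood, epithelium, nuclear oxidative phosphorylation, proteasome and histone lists. Without a filter 2 of these, nuclear oxidative phosphorylation (24 of 57 higher in GSCT and 5 lower, camera adjusted p = 0.02807) and histones (2 of 13 higher and 5 lower, adjusted p = 0.02905), passed as lower relative to other genes. Leaving out any 1 GSCT library gave 7 lists past the threshold in place of 4, and scaling by library size alone ended the call of the mitochondrial list (adjusted p = 0.526), as did no filter (adjusted p = 0.1475).

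Other scalings moved the median of all genes by 1.75 to 2.25 log2, and zebrafish replicate 3 had counts on 237 genes. Without GSCT replicate 2 the fall of actb2 (-11.14, edgeR adjusted p = 0.0761) no longer passed, nor did it without GSCT replicate 1 (-10.98, adjusted p = 0.0544).

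The comparison of grass carp with zebrafish sperm was meant to set the scale of a difference between the species. Zebrafish reads were counted on grass carp genes, so its counts and folds also reflect which zebrafish reads align to those genes. They cannot be read as differences in sperm expression alone. Of the genes at 0 in zebrafish libraries, ptpn1 was at least 79.9-fold higher in grass carp, arnt, a partner of bHLH-PAS transcription factors, at least 78.2-fold, and erbb4a, a receptor tyrosine kinase, at least 49.0-fold. Among germ cell and meiosis genes 24 of 29 tested were higher in grass carp and 3 lower (24 and 3 adjusted over the list alone). Of these ddx4 was at least 14.6-fold and msh5 at least 18.3-fold higher. Ribosomal protein genes were lower in grass carp, 43 of 45 tested (43 adjusted over the list alone), and 60 of 83, with 8 higher, without a filter, with rpl39 at 7.635 ± 2.201 CPM in grass carp and 3280 ± 3690 CPM in zebrafish (SD, n = 5 each; 1702.6 without zebrafish replicate 5).

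Of 20106 genes tested by edgeR's quasi-likelihood test, 16510 passed the adjusted threshold, 15208 higher and 1302 lower in grass carp. DESeq2 gave 19130 higher and 206 lower, RLE factors 19145 and 281, and library size alone 18375 and 522. No zebrafish library had a count on 12360 of the tested genes. The count fell to between 6092 and 6177 when 1 grass carp library was left out, because the filter then kept 7126 to 7243 genes. Camera called 7 of 17 lists, each lower in grass carp against other genes. The calls of 3 held with an estimated correlation: ribosomal proteins (camera adjusted p = 9.89e-214, and adjusted p = 5.25e-04 with an estimated correlation), RNA binding and translation factors (4.02e-24 and 0.00121) and histones and chromatin (5.18e-06 and 0.0115). The other 4 were lost: heat shock (camera adjusted p = 5.49e-07, and adjusted p = 0.0866 with an estimated correlation), epithelium, muscle and kidney (0.00126 and 0.391), nuclear oxidative phosphorylation (0.00184 and 0.561) and proteasome (0.00293 and 0.724). Without a filter 1 list passed, the ribosomal proteins, and nuclear oxidative phosphorylation was also lost without zebrafish replicate 3 (adjusted p = 0.0558) or 5 (adjusted p = 0.140). The proteasome call was lost with any library left out other than zebrafish replicate 1 (adjusted p up to 0.822). The proteasome list had a median of 2.31 while camera placed it below other genes. Of the rest, camera gave adjusted p = 0.587 for axoneme, 0.520 for sperm head, 0.693 for germ cell, 0.247 for oocyte and 0.314 for testis somatic genes. It gave adjusted p = 0.994 for blood, 0.994 for leukocyte, 0.317 for mitochondrial, 0.104 for glycolysis and 0.0527 for sex determination genes.

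DESeq2 moved the median of all genes by -3.84 log2. The edgeR calls of 3 named genes depended on 1 zebrafish library. The androgen receptor gene ar was at -2.68 ± 0.49 (adjusted p = 7.19e-04) and at -0.66 without zebrafish replicate 5 (adjusted p = 0.182). The mitochondrial gene ND4 was at -2.42 ± 0.86 (edgeR adjusted p = 0.0183), at -0.37 without zebrafish replicate 5 (adjusted p = 0.770) and at -1.60 without replicate 2 (adjusted p = 0.148). The chromatin gene hmgb1b was at -4.92 ± 0.95 (edgeR adjusted p = 9.30e-04) and at 0.96 without zebrafish replicate 4 (adjusted p = 0.312).

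The differences of GSCT from grass carp sperm were set against those of zebrafish from grass carp sperm over 26159 genes, which are not independent replicates. The covariance of the fold changes was 0.0191, against 0.0153 ± 8.53e-04 (SD) in 20 simulations of unchanged groups sharing the grass carp libraries. The correlation was 0.0255, against 0.09998 ± 0.00575. In the simulations every group, zebrafish included, had grass carp proportions and grass carp spread. Their SD thus leaves out the spread of zebrafish libraries, and the simulated correlation is not directly comparable with the real one. With the grass carp libraries divided between the comparisons, the covariance ranged from -0.0635 to 0.0652 over 20 arrangements, with a mean of 0.00365. Among 20106 genes tested in both, 33 were higher than grass carp in GSCT and in zebrafish, against 45.8 for independent lists, and 170 were lower in both, against 164. Without grass carp replicate 2 the covariance was -3.76e-04, and it was 0.0468 without replicate 1 and 0.0437 without replicate 3.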

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

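The tests of the first and second pattern below, and that of X chromosome dosage, were chosen after the results they bear on were seen. In a search of 71 groups of values for 1 library far from the rest, 12 stood out, where chance nominally gives about 1 in 20 (5%). That rate takes no account of zebrafish libraries with few counts, where single reads can set a value apart. The 12 do not hold every such value. Not among them are LOC127508753 at 14791.7 CPM in grass carp replicate 5 and hmgb1b at 805.4 CPM in zebrafish replicate 4, each far above the other libraries of its group. In grass carp replicate 1 plxnb1a was at 21147 CPM, against 2023 to 4964 in the others. In grass carp replicate 5 ier3 was at 104 CPM (22.6 to 34.5 in the others) and hspa5 at 20.6 CPM (16.4 to 17.6). In grass carp replicate 2 fosaa was at 72.9 CPM (54.9 to 59.1) and rps21 at 15.4 CPM (11.9 to 12.6). In zebrafish replicate 1 the unnamed entries held 13.8% of counts (Wilson 95% interval 13.7 to 13.9), against 63.2 to 77.9% in the others, and egr1 was at 1204 CPM (0 to 256). In zebrafish replicate 3, where 1 count is about 2053 CPM, eif5a and gapdhs were each at 2053 CPM and ckbb at 6160 CPM. In zebrafish replicate 5 hmga1a was at 535 CPM (0 to 84.4), and in zebrafish replicate 2 hspa8 was at 422 CPM (0 to 104). Entries without a gene name, which no comparison uses, held 0.404% of counts in GSCT (0.266% without replicate 1) and 57.7% in zebrafish libraries, above the 0.0424% in grass carp libraries (0.0184% without replicate 1).

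Nearly every gene had counts in GSCT and grass carp libraries, marker genes of unlike cell types included. After adjustment for gene span, sperm and germ cell lists lay above blood, leukocyte and epithelium lists by 0.163 ± 0.0771 log2 (SD over 8 libraries) and by at most 0.268 in a library (0.547 to 0.732 without the adjustment). Sperm and germ cell transcripts as a source stay open, since those lists lay above the others in each of the 8 libraries (lowest 0.0359) and no value here gives the level such transcripts would reach. Ribosomal protein genes lay at -0.45 ± 0.06 (n = 3) in GSCT and -0.46 ± 0.02 (n = 5) in grass carp relative to all genes, against 4.45 ± 3.46 in zebrafish libraries (SD, n = 5). Zebrafish values ran from -0.0109 to 8.17 and also reflect which zebrafish reads align to grass carp genes, so they are no measure of transcripts alone. Reads from genomic DNA are a candidate source that these values allow, while unspliced RNA, which also scales with gene span, was not tested, and the span used is that of the gene, not of its exons.

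Mitochondrial and rRNA genes were higher in GSCT than in grass carp libraries. For the mitochondrial genes, reads like those of the zebrafish libraries are argued against: their highest share there was 0.0270% (Wilson 95% interval 0.0166 to 0.0439), below the lowest in GSCT, 0.618% (0.594 to 0.644), and a mixture cannot exceed its parts, though zebrafish replicate 3 (0 of 487 counts, upper bound 0.783%) cannot bound the share. For rRNA they are argued against as the whole cause: LOC127507967 led in every zebrafish library, with 86.3 to 100% of the counts on the 44 called rRNA genes, and its level in GSCT leaves room for at most 9.83% of the rRNA excess of a GSCT library (upper 95% bound), while 34 of these genes, with 82.5% of the GSCT counts on them, had no zebrafish count. For LOC127507967 itself such reads stay open through zebrafish replicate 1 alone: the 8 most abundant zebrafish protein genes changed by -0.00113 to 0.00115% of counts in GSCT libraries, where reads like that library need 3.82e-04% and reads like the other 4 need 0.01093 to 0.1126%. Even counts along the mitochondrial genome (SD of log2 counts per kb at most 0.349 in a GSCT library) are consistent with mitochondrial DNA as a source, and a difference in the mitochondrial content of such sperm was not tested.

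Fold changes of neighbouring genes were alike between GSCT and grass carp: over 27931 genes adjacent pairs correlated at 0.335, against at most 0.0140 in 100 shuffles, and the changes of windows of 20 genes correlated at 0.6001 to 0.824 between GSCT libraries set against separate grass carp libraries. Reads shared between tandem copies are argued against, as genes with a symbol 5 places apart still correlated at 0.204, and X chromosome dosage as the whole cause is too, since windows with a median over 0.5 lay on 12 chromosomes. Variation between libraries of 1 group gave at most 0.129 over 10 splits of the grass carp libraries, against 0.260 for the group means, though those splits set 2 libraries against 3, and single GSCT libraries lay at 0.277, 0.270 and 0.0768 (replicate 3), the last below grass carp replicate 1 (0.124). Base composition was not tested, since no genome sequence was used here, so a difference in amplification along the genome may account for the pattern as well as one in the fish.

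Other splits of the same libraries were tested before the outcome was known. For GSCT against grass carp, 1 of 56 splits, the real one, gave 1223 genes, and the highest other gave 168. The real split ranked first, which is the most that 56 splits can show. For GSCT against zebrafish 1 of 56 gave 4906. The highest other, which set 3 zebrafish libraries against all 3 GSCT and 2 zebrafish ones, gave 4025. That split keeps all GSCT libraries together, apart from those 3 zebrafish libraries, so its count holds part of the real difference. For grass carp against zebrafish 1 of 100 drawn gave 16510, the highest other giving 350. Every other split puts libraries of both groups together, so real differences widen its spread. These ranks therefore do not exclude chance. For the number of lists, chance is not excluded by this count: 35 of 56 splits gave as many as the 1 list of GSCT against grass carp (highest other 4), 10 of 56 as many as the 4 of GSCT against zebrafish (highest other 5), and 18 of 100 as many as the 7 of grass carp against zebrafish (highest other 10). Many of these splits keep most libraries of a group together and so hold part of the real differences. A count of lists also cannot test a single call, such as that of the mitochondrial genome.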

How the results depend on the processing

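The settings that keep the unnamed entries, thin without the shallowest libraries or leave out mitochondrial and rRNA genes were chosen after seeing the data. Of 1530 values of named genes under the alternatives, 1442 kept direction and side of the threshold, 72 lost the call, 12 gained it and 4 reversed. Thinned fits gave no values for named genes and are not among the 1530, so these do not cover a change of depth. The similarity difference kept direction and side of the threshold under all 18 of its alternatives. GSCT against grass carp gave 1223 genes, 512 with all 3 groups in the fit, 102 against a log2 change of 1, 311 thinned to the smallest of the 8 libraries, and 285 to 1534 with 1 library left out. GSCT against zebrafish gave 4906, 21351 without a filter, 21528 with the stricter filter, 21612 with all groups (these test more genes), 8190 with unnamed entries kept, 198 thinned without zebrafish replicate 3, and 3646 to 6000 with 1 library left out. Grass carp against zebrafish gave 16510, 113 thinned in that way and 6092 to 20747 with 1 library left out. The difference in totals between GSCT and grass carp ran from -3222499 to -1839431.4 counts with 1 library left out. Lists past the threshold in GSCT against grass carp were 1, 3 by fry, 2 by library size alone, 2 without a filter, and 1 to 3 with 1 library left out. In GSCT against zebrafish they were 4, and 4 to 7. In grass carp against zebrafish they were 7, 3 with an estimated correlation, 2 by fry, 1 without a filter, and 3 to 9.

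Replicate numbers did not pair the libraries: no pair's deviations correlated over 0.1 (-0.00937 to 0.0490 for GSCT and grass carp, -0.0307 to 0.0654 for GSCT and zebrafish, -0.136 to 0.0411 for grass carp and zebrafish). The replicate block gave 996, 3839 and 15269 genes and 2, 4 and 8 lists in the same order. Values that reversed, for grass carp against zebrafish: ar 0.13 by DESeq2, ND4 0.52 by DESeq2 and 0.23 by RLE factors, and hmgb1b 0.96 without zebrafish replicate 4 (-4.525 to 0.96 with 1 library left out). The proteasome list reversed by fry (adjusted p 0.944) and without each grass carp library (adjusted p 0.0275 to 0.822 over all libraries left out), and the blood list without zebrafish replicate 1 (adjusted p 0.0473, and up to 0.983). The axoneme list of GSCT against zebrafish reversed by fry (adjusted p 0.0345), which does not compare it with other genes. The zebrafish direction covariance of 0.0191 ran from -3.76e-04 to 0.0468 with 1 library left out. Apart from the fry results and the counts of tested genes, the cause was not tested. Thinning all libraries to 487 counts left 0, 2 and 1 genes for the comparisons and 2 for the similarity, so it gave no value.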

Other observations

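The most abundant genes of each group were of different kinds. In grass carp libraries plxnb1a led at 6732 ± 8144 CPM (SD, n = 5), but without replicate 1 it was at 3128.5 ± 1363 CPM and a long noncoding RNA, LOC127508753, led at 3700.5 ± 7394 CPM, which rests on replicate 5. In the 5 libraries the giant muscle protein genes ttn.2 and ttn.1, among the longest known, were at 590 ± 62.9 and 479 ± 72.5 CPM. In zebrafish libraries 1 rRNA gene, LOC127507967, held 407097 ± 297930 CPM (SD, n = 5), followed by actb2 at 26959 ± 29572 CPM (15218.3 without replicate 3). In GSCT libraries a long noncoding RNA, LOC127507935, led at 5082 ± 393 CPM (SD, n = 3), against 472 ± 315 CPM in grass carp libraries (SD, n = 5). Long noncoding RNA genes made up 139 of the calls between GSCT and grass carp, 130 higher and 9 lower of 3399 tested by edgeR's quasi-likelihood test. Of 170 tRNA genes tested 79 were higher in GSCT, and of 31 snRNA genes 16 were higher.

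Among windows of 20 neighbouring genes, 21 had a median over 0.5 log2 in GSCT against grass carp, and the highest had a median of 0.87, with 18 of its 20 genes past the threshold by edgeR's quasi-likelihood test. These included mslnb (0.93 ± 0.13, adjusted p = 1.53e-04), eri2 (1.64 ± 0.28, adjusted p = 0.00129) and zbtb45 (1.37 ± 0.26, adjusted p = 0.00349). These genes were named after their values were seen.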
